A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

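Total RNA was taken from log-phase cultures of Saccharomyces cerevisiae BY4741 grown in rich medium (YPD) at 28 °C to an absorbance of 0.6. Per the labels' protocols, 50 ml of culture received 10 µg/ml b-lapachone in DMSO or the vehicle, 1% DMSO, for 1 h, and RNA was extracted with acid phenol and labelled indirectly with Cy5 and Cy3. Each of the 4 arrays carried 2 channels, RNA of a treated culture and RNA of a vehicle culture. The series' design text gives 4 biological replicates with the dyes swapped in 2 of them: treated RNA carried Cy3 on replicates 1 and 3 and Cy5 on replicates 2 and 4. The 4 arrays form 1 group, because each is itself a direct comparison.

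The authors deposited a value table with 1 value per open reading frame (ORF) and array, taken here as log2 ratios of the channels. Their scanner software, background correction, normalization, averaging of spots, log base and direction are not given in the sources used here. Values lay on both sides of 0. Column medians were -0.0227, -0.0005, -0.0176 and 0.0029 for replicates 1 to 4, so the columns had been centred in some way, and their SDs were 0.379, 0.308, 0.287 and 0.272. Base 2 is an assumption, and each fold given here depends on it. A fixed ratio of the dyes would make arrays of opposite dye orientation correlate below 0 if treatment effects outweighed dye bias. All 6 pairs of columns correlated above 0 across genes. Dye bias larger than the treatment effects could also give this in a fixed-dye table, so the form is not settled. The columns were read as running in a single direction of treatment, an assumption on which every mean given here rests. Treated over vehicle was taken as the likely direction because it is the usual form; the array titles list the vehicle sample first, and the opposite form would exchange every rise and fall.

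The table listed 6211 ORFs, and 5662 of them matched a locus tag in the R64 gene table, which was used for gene names and for the order of neighbouring genes. The other 549 kept their ORF names. No genome build is named for the arrays, and no coordinates are given. Replicates 1 to 4 had values for 5176, 5534, 5179 and 4819 ORFs. The 5112 genes with a value on at least 3 arrays were tested, 4574 of them on 4 arrays and 538 on 3. The remaining 1099 were left out, among them 544 with no value on any array. Without signal and background values, dim or saturated spots could not be told from others, and the number of arrays limits the precision.

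The mean log2 ratio of each gene was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene is said to have risen, fallen or changed only where its adjusted p was below that threshold. No further normalization was applied. Errors are SDs over arrays. In columns turned by treatment, a balanced dye swap cancels a gene's dye effect in its mean when all 4 arrays measured it. A fit with a dye coefficient tested that effect.

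The test, the 32 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The lists came from general knowledge of yeast, with the mating lists standing for the strain's own and the other cell type, and the deleted auxotrophic markers for probes with no full transcript. AAD16, in the reductase list, was not found in the gene table. Each list was tested with limma's camera on moderated t values turned into z-scores, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 32 lists. The preset form was used because the estimated correlation needs complete values; camera with an estimated correlation, and fry, were run on the 4574 genes with 4 values. Beside the calls over all genes, each list has a count adjusted over the list alone. Of genes called on 4 arrays with the same sign on each, the text names the 12 with the highest and the 12 with the lowest mean. It also names up to 4 called members of each list, or the 1 with the largest size where none was called, and 20 fixed genes whatever their values. Other genes are named as chosen after their values were seen. Results of some genes that the rule takes in are not reported here.

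The procedure was tested on simulated data: 20 simulations of b-lapachone over vehicle on 4 arrays and 5112 genes, 200 of them changed. It recovered 51.4% of genes changed by a log2 ratio of 0.5, 91.9% at 1 and 97.8% at 1.5, and 3.95% of its calls were false. A list shifted by 0.2 was called in 20 of 20 simulations, with 0.2 other lists called per simulation. The simulated genes varied independently and carried no dye effect. These rates therefore do not cover correlation between genes or dye bias, either of which could make false calls more frequent in the real data. The alternatives were a dye coefficient, centred, scaled or quantile-normalized arrays, values on 4 or on at least 2 arrays, a robust variance prior, each gene's own variance, a test against a 1.2-fold change, array weights and leaving out each replicate in turn. For lists, camera on ranks was tried as well.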

Results

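Expression microarrays compared yeast exposed to b-lapachone with yeast exposed to its vehicle, a comparison that the series' title places among responses to a DNA-damaging compound. b-Lapachone is a naphthoquinone that cellular reductases reduce and oxygen reoxidises. BY4741, the strain used, is a haploid laboratory strain of mating type a that carries his3Δ1, leu2Δ0, met15Δ0 and ura3Δ0. Cultures received 10 µg/ml b-lapachone or 1% DMSO for 1 h, and each of the 4 arrays set a treated culture against a vehicle culture (1 group, n = 4 biological replicates). The arrays gave values for 4819 to 5534 of 6211 ORFs, and 5112 genes measured on at least 3 arrays were tested. The number of arrays limits the precision: the median standard error of a gene's mean log2 ratio was 0.109.

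After 1 h with b-lapachone, gene lists for ribosome biogenesis, amino acid synthesis, drug efflux, peroxide defence and the pentose phosphate pathway lay higher than other genes, and lists for a-cell mating, the respiratory chain, ergosterol synthesis, M/G1, the proteasome and phosphate starvation lay lower (limma's camera with a preset correlation). None of these 11 list calls held with an estimated correlation, where the lowest adjusted p was 0.284. With 4 arrays that form rests on few residual degrees of freedom, so a call lost there leaves the shift undecided. The preset form is not firm support either, as it called 13 lists when the signs of replicate 3 were turned. The largest rise was in OSI1 (YKL071W), an oxidative stress-induced gene related to reductases, at a mean log2 ratio of 2.01 ± 0.62 (SD, n = 4), or 4.04-fold. It was followed by ARG1 (YOL058W), the argininosuccinate synthase of arginine synthesis, at 1.41 ± 0.33 (2.67-fold), ICT1 (YLR099C), a lysophosphatidic acid acyltransferase, at 1.37 ± 0.18 (2.59-fold), and SRX1 (YKL086W), the sulfiredoxin that repairs oxidised peroxiredoxins, at 1.35 ± 0.25 (2.55-fold). Among genes measured on 4 arrays, the largest falls were in CYT1 (YOR065W), cytochrome c1 of the respiratory chain, at -1.18 ± 0.28 (2.26-fold lower), WSC4 (YHL028W), of the WSC family of wall sensors, at -1.03 ± 0.20 (2.05-fold lower), and LEU1 (YGL009C), the isopropylmalate isomerase of leucine synthesis, at -0.97 ± 0.20 (1.96-fold lower). The direction, b-lapachone over vehicle, is likely rather than settled, because the deposited table does not state it. The opposite form would exchange every rise and fall given here. A fixed ratio of the dyes is not excluded either, and in that form the means would hold dye bias rather than treatment effects.

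Of 5112 genes tested, 155 changed (limma, Benjamini-Hochberg), 106 of them higher and 49 lower. These were 3.03% of the genes tested, each with the same sign on all arrays that measured it, and 960 genes had an unadjusted p under 0.05. At least 2-fold changes numbered 11, with 8 rises (OSI1, ARG1, ICT1, SRX1, YOR1, GPX2, CHA1 and LYS20) and 3 falls (CYT1, WSC4 and HMX1). The smallest mean log2 ratio called had a size of 0.40. Leaving out replicate 3 left 27 called genes and leaving out replicate 4 left 67, and 25 genes were called whichever replicate was left out. With each gene's own variance in place of limma's pooled one no gene was called (0 of 5112, with 690 at an unadjusted p under 0.05), a test against a 1.2-fold change called 28, and array weights raised the count to 263.

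**Figure D1:**
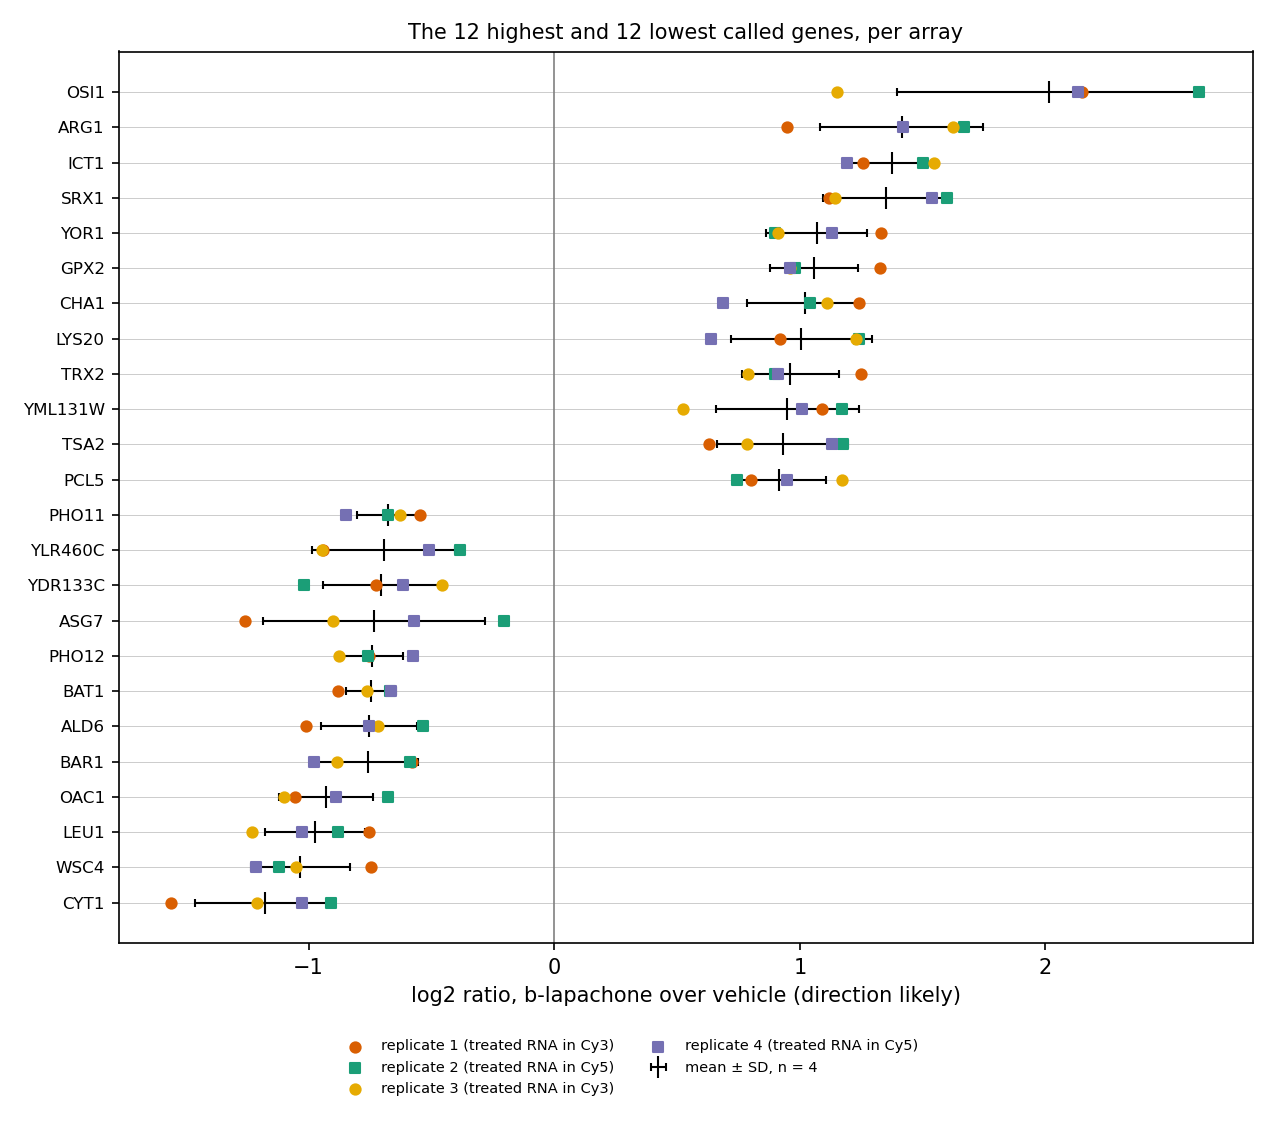
Log2 ratios of b-lapachone over vehicle (x axis, likely direction) for the 12 highest and 12 lowest called genes (y axis), with 1 point per array (circles, treated RNA in Cy3; squares, treated RNA in Cy5), and the mean with its SD (vertical mark and bar, n = 4). All 4 points of each gene lie on the same side of 0, and the means run from 2.01 for OSI1 to -1.18 for CYT1.

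Rises of at least 2-fold were also measured for YOR1 (YGR281W), an ABC transporter, at 1.07 ± 0.20, GPX2 (YBR244W), a glutathione peroxidase, at 1.06 ± 0.18, and CHA1 (YCL064C), the serine and threonine deaminase that breaks these amino acids down, at 1.02 ± 0.24. On the same log2 scale LYS20 (YDL182W), a homocitrate synthase of lysine synthesis, rose by 1.01 ± 0.29, TRX2 (YGR209C), a cytosolic thioredoxin, by 0.96 ± 0.20, and YML131W, related to reductases, by 0.95 ± 0.29. TSA2 (YDR453C), a thioredoxin peroxidase, rose by 0.93 ± 0.27 and PCL5 (YHR071W), a cyclin that directs degradation of the regulator Gcn4, by 0.92 ± 0.19. Among the falls, OAC1 (YKL120W), a mitochondrial oxaloacetate carrier, was at -0.93 ± 0.19, BAR1 (YIL015W), the protease of a cells that cleaves alpha factor, at -0.76 ± 0.20, and ALD6 (YPL061W), the cytosolic aldehyde dehydrogenase, at -0.75 ± 0.20. BAT1 (YHR208W), the mitochondrial branched-chain aminotransferase, was at -0.74 ± 0.10, PHO12 (YHR215W) and PHO11 (YAR071W), acid phosphatases, at -0.74 ± 0.13 and -0.68 ± 0.13, and ASG7 (YJL170C), a gene specific to a cells, at -0.73 ± 0.45. YDR133C fell to -0.70 ± 0.24 and YLR460C, related to reductases, to -0.69 ± 0.29. PHO11 and PHO12 are near-identical, as LYS20 and LYS21 are closely related, so cross-hybridisation leaves their separate values uncertain. Of these highest and lowest genes, ALD6, BAR1, PHO11, PHO12, ASG7 and YLR460C were no longer called without replicate 3, nor was ASG7 without replicate 4.

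In peroxide defence, 10 of 26 genes tested in the thioredoxin, glutathione and peroxide list rose and none fell (12 and 2 when adjusted over the list alone). SRX1, GPX2, TRX2 and TSA2 rose most, and the list's median log2 ratio was 0.15. The list was split, with 14 means above 0 and 12 below. Those below took in the catalases CTT1 (-0.32 ± 0.36) and CTA1 (-0.28 ± 0.23) and the glutaredoxins tested, all named after their values were seen and none called over all genes. The list lay above other genes (camera, Benjamini-Hochberg adjusted p = 1.65e-04), a call lost with an estimated correlation (adjusted p = 0.284) and on ranks (adjusted p = 0.105). The median was 0.41 on replicate 1 and 0.00 on replicate 4, and GPX2 stood highest on replicate 1, at 1.32. YAP1 (YML007W), the regulator of many of these genes, did not pass the test at 0.12 ± 0.26, with 0.50 on replicate 1 and a mean of -0.01 over the others. Without replicate 3, 5 of the 10 rises remained called, SRX1, GPX2, TRX2 and TSA2 among them.

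The quinone, aldehyde and NAD(P)H-dependent reductases moved both ways. Of 28 tested, 4 rose and 2 fell (4 and 5 when adjusted over the list alone). OSI1 and YML131W rose, and so did GRE2 (YOL151W), a methylglyoxal reductase, by 0.60 ± 0.15, while YLR460C fell. The old yellow enzymes OYE2 (YHR179W) and OYE3 (YPL171C), at 0.18 ± 0.10 and -0.19 ± 0.31, and the quinone reductase LOT6 (YLR011W), at -0.14 ± 0.28, did not pass. The list's median was -0.05 and its mean 0.04, opposite in sign, and its shift was not called (camera, Benjamini-Hochberg adjusted p = 0.803). The median lay below 0 on replicates 1 and 3 (-0.24 and -0.09) and above 0 on replicates 2 and 4 (0.13 and 0.04), a split that follows the dye. Without replicate 3, 2 of the 6 calls remained, and GRE2 and YLR460C were lost.

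The pentose phosphate pathway, which supplies NADPH, had 3 of 15 genes higher and none lower (5 and 0 when adjusted over the list alone), with 13 of the 15 means above 0. Those above 0 took in all of PRS1 to PRS5, phosphoribosyl pyrophosphate synthetases that lie outside the NADPH-supplying steps. ZWF1, whose enzyme opens the pathway and yields NADPH, did not pass at 0.11 ± 0.07 (limma, Benjamini-Hochberg adjusted p = 0.572). The PRS genes and ZWF1 were named after their values were seen. GND2 (YGR256W) and GND1 (YHR183W), the 6-phosphogluconate dehydrogenases, rose by 0.50 ± 0.19 and 0.42 ± 0.08, and TKL1 (YPR074C), a transketolase, by 0.49 ± 0.20. The list's median was 0.17 and lay between 0.16 and 0.23 on every array. Its upward shift (camera, Benjamini-Hochberg adjusted p = 3.73e-04) was lost with an estimated correlation (adjusted p = 0.284). No call in the list remained without replicate 3 or without replicate 4 (0 of 3 each).

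Among drug efflux pumps and their regulators, 8 of 26 rose and 1 fell (13 and 2 when adjusted over the list alone), and the median of 0.26 was the highest of the 32 lists. ICT1, an acyltransferase that the list holds beside the pumps, and YOR1 rose most. FLR1 (YBR008C), a transporter of the major facilitator family, rose by 0.75 ± 0.32 with 1.22 on replicate 1 and a mean of 0.60 over the others, and PDR5 (YOR153W), the main ABC drug pump, rose by 0.62 ± 0.38. PDR15 (YDR406W), a close relative of PDR5, fell to -0.85 ± 0.17 (n = 3). YOR1 and PDR5 each lie beside a gene that also rose, PXR1 at 0.46 and ATG40 at 0.67, 2 neighbours named after their values were seen. The upward shift of the list (camera, Benjamini-Hochberg adjusted p = 1.01e-05) was lost with an estimated correlation (adjusted p = 0.284). Without replicate 3 the list had 2 rises and without replicate 4 it had 5, FLR1, PDR5 and PDR15 losing their calls without replicate 3 and PDR5 also without replicate 4.

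Amino acid synthesis showed 8 rises and 2 falls among 51 genes (19 and 2 when adjusted over the list alone), with 39 means above 0 and a median of 0.20. ARG1 and LYS20 rose, as did LYS21 (YDL131W), the other homocitrate synthase, by 0.89 ± 0.23, while LEU1 and BAT1, both of branched-chain amino acid synthesis, fell. GCN4 (YEL009C), which encodes the activator of many of these genes, did not pass at 0.39 ± 0.16 (limma, Benjamini-Hochberg adjusted p = 0.065), although it did with a dye coefficient (adjusted p = 0.0427) and with array weights (adjusted p = 0.0333). The upward shift (camera, Benjamini-Hochberg adjusted p = 2.84e-06) was lost with an estimated correlation (adjusted p = 0.363) and with fry (adjusted p = 0.0626). The 8 rises became 4 without replicate 2, 4 without replicate 3 and 5 without replicate 4, and ARG1, LYS20, LYS21, LEU1 and BAT1 were called in each case. Sulphate assimilation and methionine genes did not pass as a list (1 of 23 fell, 4 when adjusted over the list alone; median -0.07; camera, Benjamini-Hochberg adjusted p = 0.0510), although without replicate 2 they did (adjusted p = 0.0219), as they did with a dye coefficient (adjusted p = 0.0417) or centred arrays (adjusted p = 0.0494). SAM3 (YPL274W), the S-adenosylmethionine permease, fell to -0.42 ± 0.16 and lost its call without replicates 2, 3 and 4 in turn. In purine synthesis none of 20 genes was called (0 by limma, also 0 when adjusted over the list alone, 4 at an unadjusted p under 0.05; median -0.03; camera, adjusted p = 0.803), with SHM2 (YLR058C) the largest in size at -0.37 ± 0.19, called only with array weights (adjusted p = 0.0466).

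Genes for DNA damage response and repair showed no shift. Of 34 tested, none was called (0 by limma, also 0 when adjusted over the list alone, and 5 at an unadjusted p under 0.05), and the median was -0.01 (camera, Benjamini-Hochberg adjusted p = 0.920). On single arrays the median was -0.07 and -0.11 on replicates 1 and 3 and 0.08 and 0.06 on replicates 2 and 4, so its sign followed the dye. RNR2 (YJL026W), the small subunit of ribonucleotide reductase, had the largest mean, 0.43 ± 0.26, and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0661), although it did with a dye coefficient (adjusted p = 0.0345) and with array weights (adjusted p = 0.0426). HUG1 (YML058W-A), a checkpoint-induced gene, was at 0.02 ± 0.28, and the recombination gene MRE11 (YMR224C) at -0.10 ± 0.11. The sign of HUG1 turned without replicate 2 and without replicate 4. TEL1 and RNR3 had values on 2 arrays each and were not tested. On 4 simulated arrays a gene changed by a log2 ratio of 0.5 was recovered in 51.4% of cases, so changes of that size in single repair genes could be missed with this number of arrays.

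Ribosome biogenesis and rRNA processing genes lay slightly above 0 together, 80 of 92, with a median of 0.14 and per-array medians from 0.10 to 0.19. No single member was called (0 by limma, also 0 when adjusted over the list alone, 20 at an unadjusted p under 0.05), and RRP36 (YOR287C) was largest at 0.42 ± 0.33, called only without replicate 2 (adjusted p = 0.0367). The upward shift (camera, Benjamini-Hochberg adjusted p = 5.65e-07) was lost with an estimated correlation (adjusted p = 0.284). RNA polymerases I and III had a median of 0.11 over 20 genes and were not called (camera, Benjamini-Hochberg adjusted p = 0.142; 0 genes by limma, 1 at an unadjusted p under 0.05), although fry called them (adjusted p = 0.0485), with RPA34 (YJL148W) largest at 0.27 ± 0.16. Of 129 cytosolic ribosomal protein genes 1 fell, RPL31B (YLR406C), at -0.43 ± 0.14 (0 when adjusted over the list alone), and it was lost without replicates 1, 3 and 4 in turn. Their median was 0.04 (camera, Benjamini-Hochberg adjusted p = 0.259).

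The respiratory chain and ATP synthase had 4 of 32 genes lower and none higher (6 and 0 when adjusted over the list alone), and 26 means below 0. Besides CYT1, COX13 (YGL191W) and COX5B (YIL111W), subunits of cytochrome c oxidase, fell to -0.61 ± 0.19 (n = 3) and -0.43 ± 0.17, and QCR2 (YPR191W), of the cytochrome bc1 complex, to -0.58 ± 0.39. The list's median was -0.13, and its downward shift (camera, Benjamini-Hochberg adjusted p = 6.23e-04) was lost with an estimated correlation (adjusted p = 0.284). The calls numbered 2 without replicate 2, 1 without replicate 3 and 1 without replicate 4, and CYT1 was called in each case. In the tricarboxylic acid cycle 3 of 21 genes rose (4 when adjusted over the list alone), among them the peroxisomal citrate synthase CIT2 (YCR005C) by 0.59 ± 0.20, and the isocitrate dehydrogenase subunit IDH1 (YNL037C) by 0.42 ± 0.05. That list, with a median of 0.05, did not pass (camera, Benjamini-Hochberg adjusted p = 0.0610), passed without replicates 1, 3 and 4 in turn (adjusted p = 0.0367, 0.0434 and 0.0349), and kept none of its 3 gene calls without replicate 3 (0).

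In glycolysis and fermentation genes the sign of the median followed the dye, although no test of a dye difference was run on the list. Their median was 0.48 and 0.36 on replicates 1 and 3, where Cy3 marked treated RNA, and -0.16 and -0.24 on replicates 2 and 4, where Cy5 did, with 0.08 for the means of 17 genes. None was called (0 by limma, 6 at an unadjusted p under 0.05, 2 higher and 1 lower when adjusted over the list alone), and PDC5 (YLR134W), a pyruvate decarboxylase, was largest at 0.90 ± 0.82 (limma, Benjamini-Hochberg adjusted p = 0.0562). Replicate 1 carried much of the PDC5 mean, with 2.06 against 0.45, 0.88 and 0.20 on replicates 2, 3 and 4, and without it the mean was 0.51. PDC5 did pass with a dye coefficient (adjusted p = 0.0127), with scaled, quantile-normalized or weighted arrays (adjusted p = 0.0184, 0.0347 and 0.0274), over genes measured on 4 arrays (adjusted p = 0.0362) and without replicates 1, 2 and 4 in turn (adjusted p = 0.0369, 0.0388 and 0.0412). The list did not pass (camera, Benjamini-Hochberg adjusted p = 0.222) and did so without replicate 4 (adjusted p = 0.0184). In it FBA1, TDH2 and TDH3 had nearly the same values (0.085 ± 0.393, 0.085 ± 0.394 and 0.085 ± 0.393). TDH1, ENO1 and ENO2 came close, at 0.084 to 0.093, and the other members ran from -0.40 to 0.90. Saturated spots could give such shared values and a split by dye, which was not tested. The TDH genes are closely related, as ENO1 and ENO2 are, so cross-hybridisation, also not tested, leaves their separate values uncertain. Among glucose-repressed genes 1 of 13 fell, the alcohol dehydrogenase ADH2 (YMR303C), at -0.50 ± 0.22, with 4 higher and 1 lower when adjusted over the list alone, a median of 0.03 and no shift (camera, Benjamini-Hochberg adjusted p = 0.474). ADH2 was lost without replicate 3 and without replicate 4.

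General stress genes were not called as a list: 2 of 32 rose (4 when adjusted over the list alone), with a median of 0.00 and 16 means on either side of 0 (camera, Benjamini-Hochberg adjusted p = 0.693). The arrays disagreed, with medians of 0.13 and 0.14 on replicates 1 and 2 and -0.16 and -0.10 on replicates 3 and 4. The 2 genes that rose were YGP1 (YNL160W), by 0.87 ± 0.35, and SPI1 (YER150W), by 0.77 ± 0.26, both related to the cell wall, and YGP1 was lost without replicate 3. Among heat shock proteins and chaperones 1 of 24 fell, HSC82 (YMR186W), at -0.46 ± 0.24, lost without replicates 2, 3 and 4 in turn (2 higher and 2 lower when adjusted over the list alone; median 0.03; camera, Benjamini-Hochberg adjusted p = 0.803). Endoplasmic reticulum folding genes had no call among 16 (0 by limma, also 0 at an unadjusted p under 0.05), a median of -0.09 (camera, adjusted p = 0.259) and HAC1 (YFL031W) largest at 0.34 ± 0.50, from 0.81 on replicate 1 to -0.27 on replicate 4 (0.18 to 0.54 when each replicate was left out). In autophagy and vacuolar proteolysis the vacuolar protease PRB1 (YEL060C) rose by 0.61 ± 0.27, with 0.21 on replicate 4 and a mean of 0.75 over the others, and was lost without replicate 3. The other 7 of that list's 8 genes did not pass, also when adjusted over the list alone, and its median of -0.04 and mean of 0.06 differed in sign (camera, Benjamini-Hochberg adjusted p = 0.693). In the proteasome 26 of 31 means lay below 0, with no call (0 by limma, also 0 when adjusted over the list alone, 4 at an unadjusted p under 0.05) and PUP1 (YOR157C) largest at -0.32 ± 0.13, called only with array weights (adjusted p = 0.0474). The downward shift of the proteasome, median -0.11 (camera, Benjamini-Hochberg adjusted p = 0.00783), was lost without replicate 4 (adjusted p = 0.0546) and with an estimated correlation (adjusted p = 0.363).

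Genes of a-cell and haploid mating were lower, the cell type of the strain itself: 3 of 11 fell (4 when adjusted over the list alone) and 9 means lay below 0. BAR1, AGA1 (YNR044W) and AGA2 (YGL032C), the last 2 encoding the a-agglutinin, fell, the agglutinin genes to -0.58 ± 0.23 and -0.53 ± 0.29. The median was -0.20, and the downward shift (camera, Benjamini-Hochberg adjusted p = 3.73e-04) was lost with an estimated correlation (adjusted p = 0.363). No call of this list remained without replicate 3 (0), and 1 remained without replicate 4. Of the alpha-cell genes 2 of 4 were tested and neither was called (0 by limma, 0 at an unadjusted p under 0.05; median 0.07; camera, adjusted p = 0.693), with MF(ALPHA)2 (YGL089C), an alpha-factor gene, at 0.20 ± 0.24. Of the deleted markers, HIS3 (YOR202W) was at 0.26 ± 0.30 and URA3 (YEL021W) at 0.14 ± 0.23, neither called (0 by limma, 0 at an unadjusted p under 0.05; median 0.20; camera, adjusted p = 0.222), and LEU2 and MET17 had no value on any array. URA3 is deleted in this strain and still had values on 4 arrays, so a value here does not by itself show a transcript.

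Of the cell cycle lists, M/G1 genes were lower and the others were not called. In M/G1, 2 of 21 fell (3 when adjusted over the list alone), FAR1 (YJL157C), an inhibitor of G1 cyclin-dependent kinase in mating, at -0.53 ± 0.17 (n = 3), and PCL9 (YDL179W), a cyclin, at -0.45 ± 0.12. The list's median was -0.17 and its shift (camera, Benjamini-Hochberg adjusted p = 0.00383) was lost with an estimated correlation (adjusted p = 0.363). PCL9 was lost whichever replicate was left out, and neither call remained without replicate 3 or replicate 4. SIC1, of the same list, had no value. In G1/S, 26 of 33 means lay below 0, with a median of -0.08 (camera, Benjamini-Hochberg adjusted p = 0.0675), no call (0 by limma, also 0 when adjusted over the list alone, 3 at an unadjusted p under 0.05), CLB6 (YGR109C) largest at -0.31 ± 0.14 and CLN2 (YPL256C), a G1 cyclin, at -0.11 ± 0.10. In G2/M, 1 of 21 fell, CLB1 (YGR108W), a mitotic cyclin, at -0.41 ± 0.14, lost without replicates 2, 3 and 4 in turn (1 when adjusted over the list alone; median -0.05, below 0 on replicates 1 and 3 and above 0 on replicates 2 and 4; camera, adjusted p = 0.693). The 8 core histone genes had no call (0 by limma, 1 at an unadjusted p under 0.05), a median of -0.11 (camera, Benjamini-Hochberg adjusted p = 0.204, and 0.0129 without replicate 1) and HTA2 (YBL003C) largest at -0.28 ± 0.24.

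Ergosterol synthesis was lower, with 2 of 25 genes down over all genes and 10 when adjusted over the list alone. ERG5 (YMR015C), a sterol desaturase, fell to -0.59 ± 0.19 (n = 3) and HMG1 (YML075C), an HMG-CoA reductase, to -0.49 ± 0.10. The median was -0.19, and the downward shift (camera, Benjamini-Hochberg adjusted p = 0.00196) was lost with an estimated correlation (adjusted p = 0.363). Neither gene was called without replicate 3 or replicate 4 (0). In phosphate starvation, 3 of 16 genes fell and 1 rose (4 and 2 when adjusted over the list alone). PHO11 and PHO12, near-identical and open to cross-hybridisation, enter these counts and the list test as 2 genes, although they may be a single measurement. The acid phosphatases PHO11, PHO12 and PHO5 (YBR093C) fell, PHO5 to -0.58 ± 0.19, while PHM8 (YER037W), a phosphatase, rose by 0.41 ± 0.11 and was lost whichever replicate was left out. The phosphate list's median was -0.11, and its shift (camera, Benjamini-Hochberg adjusted p = 0.0489) was lost without replicate 2 (adjusted p = 0.126), without replicate 4 (adjusted p = 0.111), with a dye coefficient, on ranks and with an estimated correlation (adjusted p = 0.363). None of its 4 gene calls remained without replicate 3 (0), and 2 remained without replicate 4.

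Metal and wall lists were not called as lists. In iron uptake and mobilisation 2 of 28 fell (2 when adjusted over the list alone): HMX1 (YLR205C), the haem oxygenase, to -1.03 ± 0.45 (n = 3), and FIT1 (YDR534C), a wall mannoprotein of siderophore uptake, to -0.43 ± 0.14 (median -0.04; camera, Benjamini-Hochberg adjusted p = 0.229). Among 10 copper and zinc genes the metallothionein genes CUP1-1 (YHR053C) and CUP1-2 (YHR055C) fell to -0.61 ± 0.34 and -0.59 ± 0.37 (2 when adjusted over the list alone; median -0.11; camera, adjusted p = 0.139), and as these copies are near-identical their values count as a single measurement. Among 23 cell wall genes 2 rose (4 higher and 5 lower when adjusted over the list alone): GSC2 (YGR032W), a glucan synthase subunit, by 0.78 ± 0.55 (1.58 on replicate 3, and a mean of 0.51 without it), and RLM1 (YPL089C), a regulator of wall genes, by 0.75 ± 0.18 (n = 3; median 0.06; camera, Benjamini-Hochberg adjusted p = 0.581). RLM1 lies beside YPL088W, which also rose, by 0.74, and was named after its value was seen. Of these 6 genes none was called without replicate 3, and CUP1-2 was lost whichever replicate was left out.

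Across the 32 lists, 5 lay higher and 6 lower by camera with the preset correlation, and with an estimated correlation 0 of the 32 passed, the lowest adjusted p being 0.284. Pentose phosphate and phosphate starvation lost their calls although their estimated correlations, -0.028 and 0.0090, lay below the preset 0.01. A higher correlation between genes therefore does not account for the loss in these lists. In the other called lists the estimate lay above the preset value, from 0.015 for the respiratory chain to 0.235 for a-cell mating. There the p-values of the preset form may be too small. With the signs of replicate 3 turned, the preset form called 13 lists. With fry, which asks whether a list's genes move one way on balance, 7 lists passed: peroxide defence, pentose phosphate, drug efflux, ribosome biogenesis, RNA polymerases I and III, the respiratory chain and ergosterol synthesis.

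**Figure D2:**
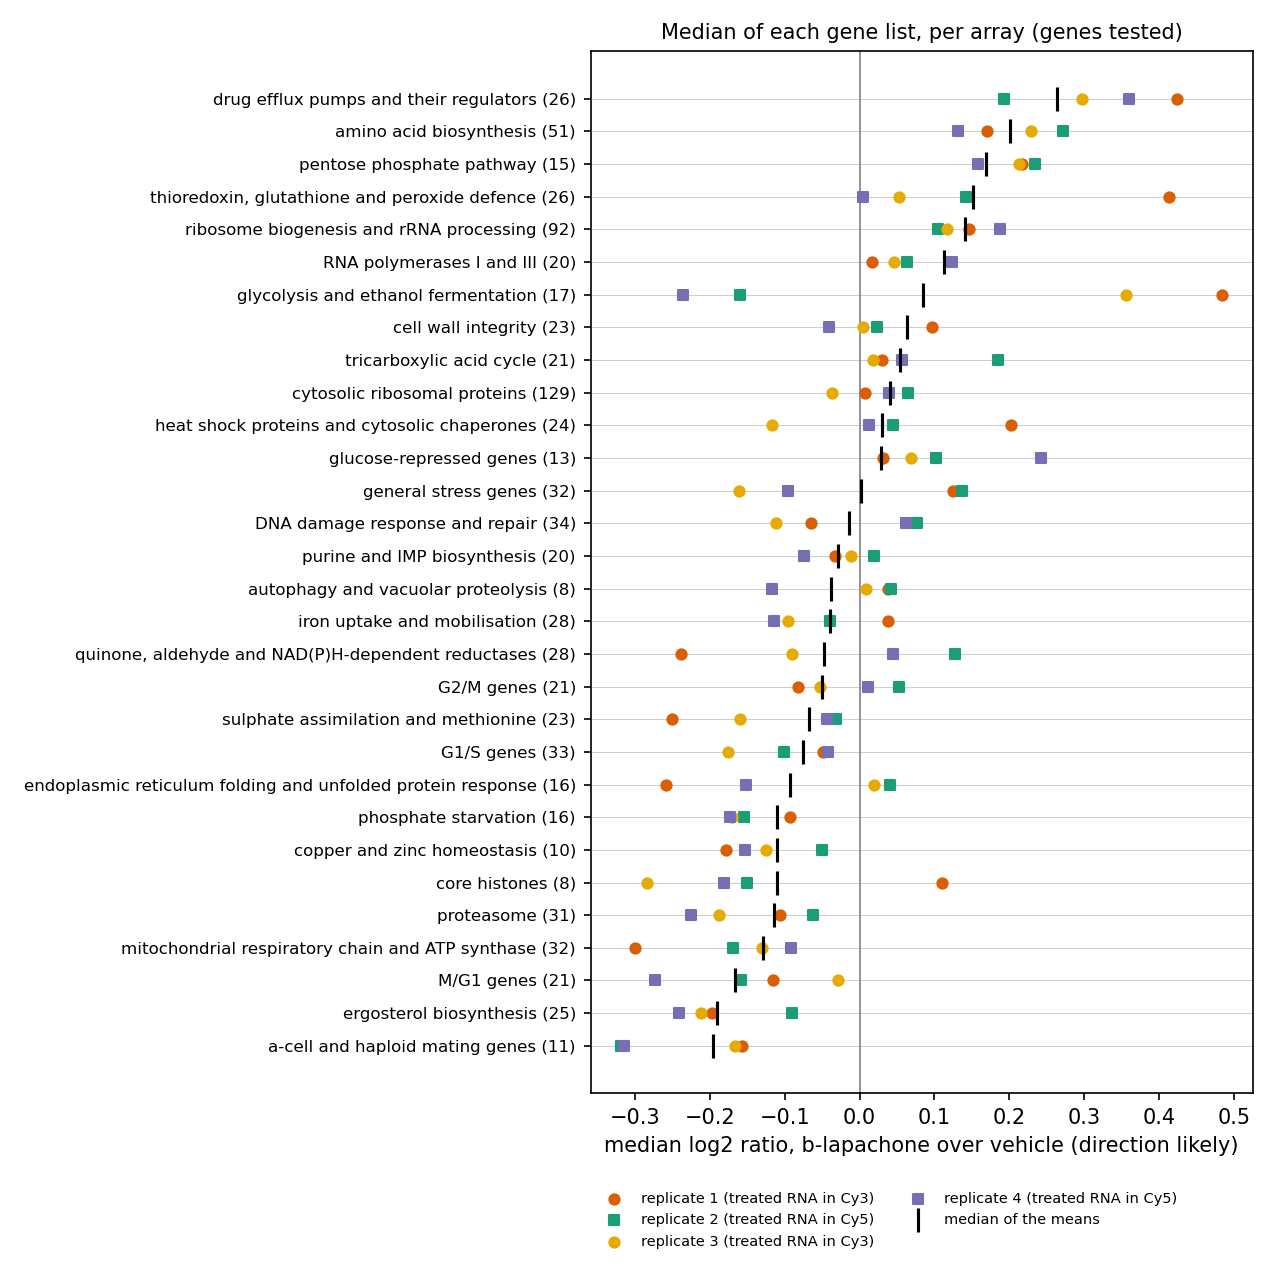
Median log2 ratio of b-lapachone over vehicle (x axis, likely direction) for gene lists with at least 8 genes tested (y axis, number tested in brackets), with 1 point per array (circles, treated RNA in Cy3; squares, treated RNA in Cy5) and a vertical mark for the median of the gene means. Drug efflux lies highest, at 0.26, and a-cell mating lowest, at -0.20, with all 4 arrays on the same side of 0 for each, while glycolysis lies above 0 on replicates 1 and 3 and below 0 on replicates 2 and 4.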

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

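Both tests of the dye pattern were chosen after the result was seen; the counts over sign patterns were not.

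Among the named genes measured on 4 arrays and the lists, 4 of 108 groups of 4 array values had 1 array standing apart from the others by Dixon's criterion, where chance gives about 5.4. GPX2 was at a log2 ratio of 1.32 on replicate 1, against a mean of 0.967 over the others. FLR1 was at 1.22 on replicate 1, against 0.598. YAP1, which did not pass the test, was at 0.503 on replicate 1, against -0.01. PRB1 was at 0.212 on replicate 4, against 0.748.

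Turning the sign of whole arrays gives 8 patterns, too few for a share under 0.05. The real pattern was the 1 of 8 with as many as 155 genes, and the highest of the others, the pattern that follows the dye, called 1. For lists, 2 of 8 patterns gave at least the 11 shifted lists of the real one, the highest other, with replicate 3 turned, giving 13.

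Arrays of opposite dye orientation agreed less across genes (mean Pearson r 0.271, SD 0.143 over 4 pairs) than arrays of the same orientation (0.439 over 2 pairs). That gap rests on replicate 1, since among the other replicates the opposite pairs gave 0.294 and 0.444 and the pair of the same orientation 0.393. The mean of 0.271, above 0 by more than its spread, argues against a fixed ratio of the dyes only if treatment effects outweighed dye bias. Larger dye bias would give the same sign in such a table, so this test cannot decide. Dye bias spread over many genes stays open: the dye coefficient had an unadjusted p under 0.05 in 499 of 5112 genes, where 255.6 are due by chance and the other pairings of the arrays gave 118 and 125, a criterion that replaced an adjusted p after that had given 2 genes of 5112. Glycolysis, reductase, DNA damage and G2/M genes had medians whose sign followed the dye. For glycolysis they ran from 0.48 and 0.36 with treated RNA in Cy3 to -0.16 and -0.24 in Cy5. Of the 8 sign patterns of 4 arrays 1 follows the dye, so some of the 32 lists are due to show it by chance. Saturated spots were not tested as a cause. No biological explanation was tested, as the design names none for the dye.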

How the results depend on the processing

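All alternatives here were chosen before the data were examined. The count of 155 changed genes (106 higher, 49 lower) stayed within 1.5 times with a dye coefficient (223, 154 of them shared), centred, scaled or quantile-normalized arrays (153 to 191), values on 4 or at least 2 arrays (175 and 122) and a robust prior (185). Array weights, lowest for replicate 1, gave 263 (173 higher, 90 lower). A test against a 1.2-fold change gave 28 (20 higher, 8 lower), as its stricter null requires. Each gene's own variance gave 0 changed, 0 higher and 0 lower (690 at an unadjusted p under 0.05), and 0 at 2-fold; a single gene then has 3 degrees of freedom or fewer. Genes changed at least 2-fold numbered 11, and 77 when counted from 1.5-fold. Leaving out each replicate gave 27 to 179 genes (21 to 128 higher, 6 to 54 lower), with the fewest without replicate 3 and then 67 without replicate 4 (52 higher, 15 lower); the cause was not tested, and 179 without replicate 1 and 164 without replicate 2 came from as many arrays. Lists higher and lower numbered 5 and 6, 0 and 0 with an estimated correlation, 5 and 2 with fry, and 5 to 7 and 4 to 7 without each replicate; the estimated and fry forms used the 4574 complete genes. The dye coefficient called 2 genes, also with centred arrays.

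Of 1100 values of named genes under the alternatives, 890 kept their direction and side of the threshold, 192 lost and 15 gained a call, and 3 changed sign, all in genes that were not called. These were YAP1 (-0.014 to 0.17 over the leave-one-out fits) and HUG1 (-0.088 to 0.14); the cause was not tested. Of 288 list values, 257 kept their side, 22 lost and 9 gained a call. Tests of single spots or of their median were not run, as the table holds 1 value per ORF, and without a signal column no trend on intensity could be fitted and signal over background is unknown. The main test already used the pairing, as each value is a ratio of a treated and a vehicle culture on the same array. With 1 group no further paired analysis was possible.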

Other observations

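The genes in the next 2 paragraphs, and the tests on LEU1, BAT1 and OAC1, were chosen after the values were seen, and the neighbour tests after some pairs had been noticed.

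Beyond the genes already named, the rises in peroxide defence took in the mitochondrial peroxiredoxin PRX1 (0.88 ± 0.21, SD, n = 4), cytochrome c peroxidase CCP1 (0.77 ± 0.18), thioredoxin reductase TRR1 (0.68 ± 0.21), the peroxiredoxin TSA1 (0.58 ± 0.26) and the superoxide dismutases SOD1 (0.48 ± 0.17) and SOD2 (0.43 ± 0.13). TRX1, the thioredoxin closely related to TRX2 but not a member of the peroxide defence list, fell to -0.56 ± 0.16 where TRX2 rose by 0.96. The external NADH dehydrogenase NDE1 fell to -0.49 ± 0.14. The other efflux genes that rose were SNQ2 (0.59 ± 0.11), TPO2 (0.56 ± 0.24), PDR10 (0.54 ± 0.17) and TPO1 (0.41 ± 0.08). Without replicate 3 none of these kept its call except TRX2 and PRX1, and without replicate 4 TSA1, SOD1, SOD2, NDE1, PDR10 and TPO1 lost theirs. TSA1, SOD2 and TPO1 also lost it without replicate 2, and TPO1 without replicate 1.

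Further rises in the amino acid synthesis list included CPA1 (0.81 ± 0.14), ARG7 (0.44 ± 0.18), LYS12 (0.64 ± 0.37) and LYS4 (0.47 ± 0.25). The arginase CAR1 rose by 0.82 ± 0.26 and the proline oxidase PUT1 by 0.90 ± 0.32 (n = 3), genes of amino acid breakdown like CHA1 at 1.02, and no list of such genes was tested. The hexose transporters HXT1 and HXT3, closely related in sequence, rose by 0.65 ± 0.25 and 0.70 ± 0.45. The fatty acid desaturase OLE1 and its activator MGA2 rose by 0.62 ± 0.16 and 0.57 ± 0.24, the calmodulin-dependent kinases CMK1 and CMK2 by 0.47 ± 0.25 and 0.78 ± 0.36, and the mitotic inhibitor kinase SWE1 by 0.51 ± 0.05. TEC1, a regulator of filamentous growth and mating genes, fell to -0.61 ± 0.12. Among these, CPA1, PUT1 and CHA1 were called whichever replicate was left out, and the others lost their call at least without replicate 3. ARG7, LYS4, MGA2, SWE1 and CMK1 also lost it without replicate 4, ARG7, LYS12 and LYS4 without replicate 2, and LYS4 and CMK1 without replicate 1.

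LEU1, BAT1 and OAC1, known targets of the regulator Leu3, fell (-0.97, -0.74 and -0.93) while ARG1, LYS20 and LYS21 rose. A dye bias of these genes is argued against, since the largest of their dye coefficients was 0.158 of the gene's mean. That holds only if the columns run in a single direction of treatment. With a fixed ratio of the dyes the mean would itself be the dye term. Lower transcription of Leu3 targets stays open. LEU4, ILV2, ILV3, ILV5 and GDH1 had a median log2 ratio of 0.0098, at the 59.4th percentile of 10000 random lists of 5 genes, but these genes leave out the 3 that fell and lie on both sides of 0, so they exclude nothing.

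Genes that lie next to each other on a chromosome moved together more than shuffled pairs. Over 3901 adjacent pairs the mean log2 ratios correlated at r = 0.107, where the upper two-sided 0.05 bound of shuffled pairs was 0.030. In 6 pairs both genes were called with the same sign, where 1.87 were due by chance (one-sided permutation p = 0.0121, 10000 permutations). Among the 6 were PXR1 and YOR1, ATG40 and PDR5, and RLM1 and YPL088W. As some pairs had been noticed before this count was made, its p is not independent support. Overlapping sequence is argued against as the whole cause, since pairs at least 200 bp apart still correlated (r = 0.109 across pairs; upper two-sided 0.05 bound of shuffled pairs 0.033). Shared array position or processing may contribute, as the deviations of single arrays from the gene means also correlated between neighbours (r = 0.0871 against 0.022). Promoters shared by divergent neighbours may contribute too, since divergent pairs correlated more than convergent ones by 0.0924, close to the same bound of shuffled orientations at 0.0882, and these data leave both open.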
